A study of Mus musculus with 4 samples.

How the data were processed

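Nuclei were isolated from hearts of mice lacking Gpnmb that were taken 7 days after ligation of the left anterior descending coronary artery, and droplet-based 3-prime single-nucleus libraries were sequenced. The labels assigned all 4 libraries to the same genotype, treatment and tissue, so there was 1 group and no contrast between groups was made. Per the labels' protocols, equal numbers of cells from 3 hearts were mixed for each group, and the sources used here do not say which hearts entered which library. The 4 libraries are named by the replicate number in their labels. Other genotypes and uninjured hearts were not analysed here.

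The deposited values were whole-number UMI counts per gene and barcode for 32285 genes, with no normalization. Per the submitters' processing notes, the counts were made with Cell Ranger against the mouse genome build mm10; the Cell Ranger version, and whether reads in introns or only those on the sense strand were counted, are not given in the sources used here. The lowest barcode total was 500 UMIs and the lowest number of genes per barcode was 123. No 2 libraries were duplicates: the chi-square of their summed counts per degree of freedom lay between 29.1 and 189 over the 6 pairs. Coordinates and strands were read from the GENCODE annotation of GRCm38, the same assembly as mm10.

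Barcodes with fewer than 300 genes or more than 10% mitochondrial UMIs were removed (358 barcodes). Doublets were scored per library as the share of simulated doublets (2 per barcode) among the neighbours of each barcode, and the highest-scoring barcodes were removed at 0.8% per 1000 barcodes, which took out 1836 barcodes, between 4.83% and 6.79% per library. The remaining 28236 nuclei were normalized to their total, log-transformed and reduced to 30 principal components of 2000 variable genes. Neighbours (16 per nucleus, 4 from each library) were joined in a shared-neighbour graph and clustered with leidenalg 0.10.2 at a resolution of 1, which gave 30 clusters. Gpnmb, Gpr39, Xist, Tsix, Y-linked and mitochondrial genes and all genes of the fixed lists were kept out of clustering. Clusters were named from 17 marker sets fixed before the data were examined: a name needed at least 3 markers at a log2 fold of at least 1 over the median cluster, no second class with markers at 0.2 of their level elsewhere, a median doublet score of at most 0.75 and fewer than 2 markers of another class among the 10 leading genes. Clusters with a median UMI count under 1/3 of their library's and no marker among the leading genes stayed unnamed. The class names are shorthand for clusters resembling that class. Fibroblasts, macrophages and cardiomyocytes were clustered again at a resolution of 0.5 and given states from fixed state markers. The neighbour rule and the naming rules were revised after a run had shown clusters that followed 1 library, and that run had also shown Gpr39 by cluster; the revision came before any test across genes, and the unrevised version is kept among the alternatives.

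UMI counts were summed per library and class or state and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) with library as a term. Classes with at least 20 nuclei in every library were tested, which left 8 classes. A class was compared with the mean of the other classes, and a state with its counterpart in the same libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Counts of calls cover genes that were neither markers nor among the 3185 genes used for clustering, since clusters and sums come from the same nuclei. Differences between states and classes are in part a product of the clustering. Their edgeR p-values set them against the spread between 4 libraries, which the class fit pools over its 8 classes. The 16 gene lists were tested with limma 3.58.1 (camera, preset correlation 0.01, and again with an estimated correlation), adjusted over the lists of 1 comparison. The lists were chosen before the data were examined. Camera compares a list's genes with the other genes tested. With the preset correlation its p-values do not measure how steady a list was over libraries. With an estimated correlation it rests on the residual degrees of freedom of the fit, which are few between states. Larger p-values there do not by themselves show correlated genes. The planned limma test of a list's own genes, fry, differed from camera in both ways. Of the lists that passed camera, only matrix proteins failed fry, in activated fibroblasts (fry adjusted p = 0.13) and between the macrophage states (0.11). In macrophages every list passed fry except growth factors (fry adjusted p = 0.44) and the cell cycle (0.30). Cytokines and interferon response there, which did not pass camera, had fry adjusted p of 1.4e-12 and 2.3e-09. Elsewhere, fry also passed growth factors in activated fibroblasts (0.029), cytokines between the macrophage states (0.038), and both in stressed cardiomyocytes (0.0054 and 0.019). In 63 of the 64 tests of a list, the count of called members adjusted over the list alone equalled that over all genes tested; the exception is given with its result. Median, mean and test differed in sign for 10 of the 64, none of which passed. Levels of single genes are CPM of the summed counts, scaled by TMM where a comparison between states or with other classes is given.

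Genes were named by a rule fixed before the data were examined: Gpnmb and Gpr39 always; from each list, in order of its camera p, up to 2 called genes with the largest rise and 2 with the largest fall, with the same direction in all 4 libraries, to about 24 genes; and 4 per direction from outside the lists, markers and clustering genes at a mean of at least 20 CPM. The tests were tried on simulated data with known changes: of genes changed by 1.5 on the log2 scale, edgeR called 94.7% for macrophages against the other classes, 100% for activated fibroblasts, 97.7% for the macrophage states and 90.8% for stressed cardiomyocytes, with 1 to 3 calls among the unchanged genes. Simulated sums had groups given in advance, so these rates do not cover calls that arise from clustering the same nuclei. Shares carry exact Clopper-Pearson 95% intervals per library, and a count of 0 allows up to 3 UMIs; both cover counting error only.

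Alternatives chosen before the data were examined were a stricter filter (500 genes, 5% mitochondrial UMIs), no doublet removal, a resolution of 2, list genes kept for clustering, DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, no library term, an estimated correlation for the lists, nuclei thinned to 1000 UMIs and leaving out each library. Neighbours drawn from all nuclei, the same with the unrevised naming rules, and comparisons without sub-clusters led by cell cycle, interferon or other unrelated genes were added after seeing the data. The lists were planned for the estimated correlation, no library term and leaving out each library; their tests under the other settings were also added after seeing the data. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, Matplotlib 3.10.9 and R 4.3.3.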

Results

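Single-nucleus RNA profiles were collected from infarcted hearts of Gpnmb-knockout mice 7 days after ligation of the left anterior descending coronary artery. Gpnmb encodes a transmembrane glycoprotein of macrophages, and the title of the series names GPR39, an orphan G protein-coupled receptor, as its binding partner in cardiac repair. The 4 libraries held 8171, 8576, 6114 and 7569 barcodes with 35954788, 42866340, 30682501 and 43927599 UMIs. Their median depths were 2305, 2895.5, 2589.5 and 2895 UMIs per barcode. After filtering, 7584, 7915, 5750 and 6987 nuclei were kept. All libraries shared genotype, injury and day, and nothing states that they came from separate animals. The comparisons are therefore between cell classes and states within the libraries. Their edgeR p-values are set against the spread between libraries, which may be technical in part. Y-linked transcripts (538 CPM in library 4, 0.224 to 0.681 CPM in the others) and Xist (0.424 against 1025 to 1243 CPM) showed that library 4 came from other animals than libraries 1 to 3.

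Fibroblasts, cardiomyocytes and endothelial cells made up most of the nuclei. Fibroblasts accounted for 23.1% ± 2.68 of the nuclei (SD, n = 4), cardiomyocytes for 22.6% ± 5.03 and endothelial cells for 20.4% ± 0.699. Macrophages accounted for 10.3% ± 3.24, with values of 10.0%, 14.7%, 9.65% and 6.87% in libraries 1 to 4. Pericytes made up 4.16% ± 0.987, endocardial cells 4.15% ± 1.46, lymphatic endothelial cells 1.77% ± 0.547 and smooth muscle cells 1.30% ± 0.462. B cells were found as 42 nuclei in all. A further 12.1% ± 0.861 stayed unnamed, most of them (2993 nuclei) because markers of 2 classes were present together. With the sub-clusters led by genes of another kind or class set aside, an alternative added after seeing the data, the unnamed share was 19.1% and the cardiomyocyte share 16.9%. The unnamed share was 28.1% and the fibroblast share 10.6% with neighbours drawn from all nuclei and the unrevised naming rules, an alternative added after seeing the data. Nuclei keep different shares of each cell type's RNA and of the cells themselves, so the shares describe the nuclei recovered.

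**Figure D1:**
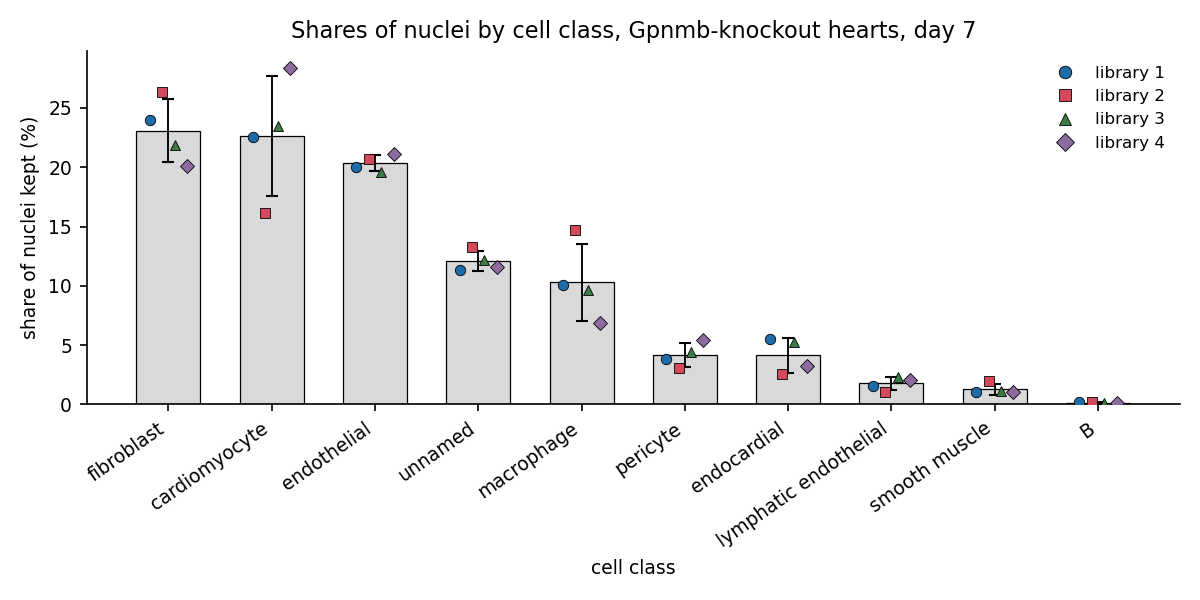
Share of nuclei kept (%, vertical axis) in each cell class; bars give the mean and error bars the SD over 4 libraries, and each symbol is 1 library. The macrophage share was highest in library 2 (14.7%), which also had the lowest cardiomyocyte share (16.2%).

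The states within 3 classes differed between the libraries. Activated fibroblasts, named from markers such as Postn and Cthrc1, made up 41.3%, 78.2%, 43.0% and 33.8% of the fibroblasts in libraries 1 to 4, and resting fibroblasts 56.0%, 20.2%, 54.4% and 63.1%. Of the 4 sub-clusters with this name, 1 (1445 nuclei) had Postn and Cthrc1 among its raised markers and 1 (389 nuclei) had Cthrc1, whereas 1426 and 137 nuclei were named from others, such as Ddah1 and Kif26b. In that order they scored 1.08, 0.087, 0.31 and 0.48 for the activated markers. Of the 389 nuclei with the lowest score, 259 were of library 2. Macrophages named from markers such as Trem2 and Spp1 made up 22.7%, 41.0%, 26.5% and 17.5% of the class, and macrophages with resident markers such as Lyve1 and Timd4 made up 30.2%, 17.3%, 35.5% and 42.7%. Of the Trem2 and Spp1 state, 110 nuclei were named from Spp1, Lgals3 and Cd9 without Trem2, scored about as high for the resident markers (0.711) as for those of the state (0.749), and were also led by genes such as Reln and Tek. With them set aside, an alternative added after seeing the data, the share ran from 12.8% to 39.1%. Cardiomyocytes with stress markers such as Ankrd1 and Nppb made up 11.2%, 22.9%, 8.53% and 6.65%. The means of these shares depended on the clustering: the activated share was 49.1% ± 19.8 (SD, n = 4) and 17.6% with the stricter filter, and it ran only from 30.1% to 41.3% under the unrevised rules, lowest in library 2. The Trem2 and Spp1 share was 26.9% and 7.50% with the list genes kept for clustering, and the stressed share was 12.3% ± 7.30 and 49.9% at a resolution of 2. The state with no name among macrophages included 1073 nuclei with a median of 837 UMIs, 0.339 of the median of their libraries.

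**Figure D2:**
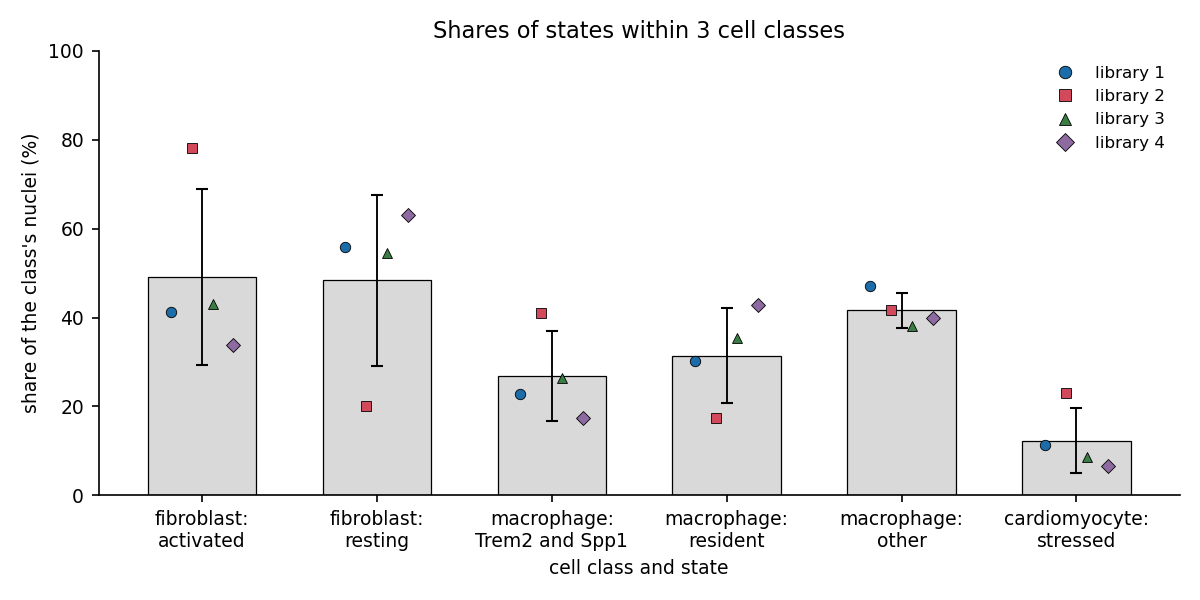
Share of a class's nuclei in each state (%, vertical axis) for fibroblasts, macrophages and cardiomyocytes; bars give the mean and error bars the SD over 4 libraries, and each symbol is 1 library. Library 2 had the highest shares of activated fibroblasts (78.2%), Trem2 and Spp1 macrophages (41.0%) and stressed cardiomyocytes (22.9%).

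The targeted gene was almost absent from the counts. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929, plus strand, mm10) had 8 UMIs among 130945657 UMIs of 28236 nuclei, with 4, 1, 0 and 3 UMIs in libraries 1 to 4. No Gpnmb UMI was found in 2959 macrophage nuclei with 4677494 UMIs, which allows up to 0.641 CPM. The same count of 0 was found in the 881 Trem2 and Spp1 macrophages. The labels do not describe the allele, so it is not known whether the counted 3-prime end lies in a deleted part of the gene, and wild-type hearts were not analysed here.

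Gpr39 (ENSMUSG00000026343, chromosome 1, 125676995 to 125873862, plus strand, mm10) was highest in fibroblasts among the 8 tested classes. Its level was 225 ± 117 CPM in fibroblasts (SD, n = 4; 150 to 399), 70.5 ± 39.0 in smooth muscle cells, 35.5 ± 8.97 in lymphatic endothelial cells and 27.3 ± 5.09 in macrophages. Pericytes had 23.6 ± 9.02 CPM, endocardial cells 19.9 ± 11.8, endothelial cells 18.4 ± 4.92 and cardiomyocytes 3.12 ± 1.06. In alternatives added after seeing the data, smooth muscle cells had 138 ± 128 CPM with neighbours from all nuclei. Fibroblasts had 354 ± 67.4 CPM under the unrevised rules. Against the mean of the other classes, Gpr39 was higher in fibroblasts by 3.23 on the log2 scale (SE 0.0961, edgeR adjusted p = 3.7e-24) and in smooth muscle cells by 1.50 (SE 0.189, edgeR adjusted p = 9.2e-08). It was lower in cardiomyocytes, with a log2 fold change of −2.89 (SE 0.153, edgeR adjusted p = 1.6e-18). Endothelial cells (−0.77, edgeR adjusted p = 4.5e-05) and endocardial cells (−0.69, edgeR adjusted p = 0.0078) stayed under the fold limit, but both were called lower at a resolution of 2 (−1.33 and −1.08), with neighbours from all nuclei (−1.51 and −1.34) and under the unrevised rules (−1.81 and −1.40), and endothelial cells also with list genes kept for clustering (−1.20). Lymphatic endothelial cells (0.28, edgeR adjusted p = 0.28), pericytes (−0.36, edgeR adjusted p = 0.21) and macrophages (−0.31, edgeR adjusted p = 0.15) did not differ detectably from that mean. The smooth muscle call was lost at a resolution of 2 (0.90), with list genes kept for clustering (0.72) and under the unrevised rules (0.61). Macrophages became lower by call with list genes kept (−1.28) and under the unrevised rules (−1.03), and were at 0.01 without library 2. Unnamed nuclei had 225 ± 82.8 CPM, and mesothelial nuclei had enough nuclei for a test in 4 alternatives, 2 of them added after seeing the data, with Gpr39 higher by 4.46 to 5.12, above the fibroblast difference. T or NK nuclei had enough for a test under the unrevised rules alone, an alternative added after seeing the data, and were called higher (1.25, edgeR adjusted p = 0.036).

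At least 1 Gpr39 UMI was found in 26.8% ± 13.5 of fibroblast nuclei (SD, n = 4; mean of the library medians 2502 UMIs) and in 3.08% ± 1.35 of cardiomyocyte nuclei (8054 UMIs). With every nucleus thinned to 1000 UMIs the shares were 15.1% ± 7.48 and 0.438% ± 0.297, leaving out 461 and 128 shallower nuclei. Macrophage nuclei gave 3.37% ± 0.941 (1242 UMIs), and 2.27% ± 1.20 after thinning without 1025 nuclei. As a share of the fibroblast level, Gpr39 stood at 1.47% in cardiomyocytes, 13.8% in macrophages and 31.7% in smooth muscle cells, where the median of the fibroblast markers stood at 2.97%, 18.2% and 29.7%. The last part of Gpr39 overlaps Lypd1 (ENSMUSG00000026344, 125867622 to 125913101, minus strand), which had 0.0101 UMIs per Gpr39 UMI in fibroblasts.

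Macrophages, named in the title as the source of the protein, were compared with the other classes. Their lysosome genes were higher as a group: of 24 measured, 16 were higher by call and 0 lower. Among them were Ctss, a lysosomal cysteine protease (log2 fold change 5.31, SE 0.154), and Atp6v0d2, a subunit of the vacuolar proton pump (5.20, SE 0.254). Of 16 efferocytosis genes, 6 were higher, with Cd300lf, a receptor for lipids of dying cells (5.70), and Dock2, an activator of Rac (5.66), and 1 was lower, the integrin subunit Itgb3 (−1.27). Of 15 lipid handling genes, 7 were higher, among them the scavenger receptor Msr1 (5.54) and the acyltransferase Lpcat2 (3.64). These lists passed camera at adjusted p of 1.2e-14, 1.1e-10 and 6.9e-05, and at adjusted p = 1.8e-05, 1.8e-05 and 0.0099 with an estimated correlation.

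The other lists did not pass camera in macrophages. Of 6 cytokine and chemokine genes measured among 22 listed, 3 were higher, with Ccl9 (4.81) and Ccl6 (4.55). The genes Csf1 (−1.51) and Cxcl12 (−1.40) were 2 lower ones, and the list had a camera adjusted p of 0.057. Of 16 interferon response genes 4 were higher, with Ifi207 (3.22) and Ifi204 (3.14), and Ifi44 was lower (−1.03; camera adjusted p = 0.065). Of 22 matrix proteins 4 were lower, with the basement membrane collagens Col4a2 (−1.63) and Col4a1 (−1.37; camera adjusted p = 0.069). Among 16 genes of the TGF-beta pathway, Tgfbr1 (1.79) and Tgfb1 (1.02) were higher, and Ltbp1 (−2.32) and Tgfb2 (−2.04) were among 4 lower ones. Of 20 matrix crosslinking and turnover genes, Mmp19 (1.66) and Timp2 (1.13) were higher and 7 were lower, with the proteases Adamts1 (−1.94) and Adamts12 (−1.92). The calcium handling genes Cacnb2 (−1.07) and Jph2 (−1.06) were lower. The other 7 lists, on complement, glycolysis, immediate early genes, growth factors, fatty acid oxidation, oxidative phosphorylation and the cell cycle, had camera adjusted p between 0.26 and 0.98. Outside the lists, Was (4.84), Kcnab2 (4.31), Rgs10 (4.23) and AB124611 (4.19) had the largest rises. Fam124a (−2.72), Sorbs2os (−2.67), Lrig1 (−2.65) and Chn1 (−2.51) had the largest falls, and Sorbs2os lost its call under the unrevised rules (−1.53, edgeR adjusted p = 1). In all, 767 genes were called higher and 880 lower among 9466 counted. The count lower was 585 at a resolution of 2, and the count higher 1526 with no filter on low counts. Without library 2, cytokines (camera adjusted p = 0.0053), interferon response (0.020) and matrix proteins (0.042) also passed, and without library 3 cytokines and interferon response (both 0.047). With all libraries and an estimated correlation, camera adjusted p was 0.21 for cytokines, 0.60 for interferon response and 0.71 for matrix proteins. In settings added for the lists after seeing the data, 5 to 8 lists passed in macrophages under every change of the filter on nuclei or of the clustering, among them lysosome, efferocytosis and lipid handling each time. Leaving out library 2 ended the calls of Itgb3 (−0.90), Cacnb2 (−0.92), Jph2 (−0.98), Tgfb1 (0.98) and Ifi44 (edgeR adjusted p = 0.062); leaving out library 3 ended those of Tgfb1 (0.96) and Ifi44 (0.19), and library 1 or 4 that of Ifi44 (0.11 and 0.081). At a resolution of 2, Cxcl12 (−0.80), Tgfb1 (0.91), Timp2 (0.98), Jph2 (−0.95) and Ifi44 (−0.21) were not called.

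Col11a1 and Fn1 were higher in activated than in the other fibroblasts. Of 22 matrix proteins 9 were higher and 0 lower (camera adjusted p = 8.8e-08; adjusted p = 0.68 with an estimated correlation), with the fibrillar collagen Col11a1 at a log2 fold change of 4.08 (SE 0.157; 249 ± 73.2 against 15.3 ± 9.82 CPM, SD, n = 4) and fibronectin, Fn1, at 2.88 (SE 0.203). Of 23 cell cycle genes 19 were higher (camera adjusted p = 8.7e-16; adjusted p = 0.33 with an estimated correlation), with the spindle checkpoint kinase Bub1 (4.28) and the spindle protein Aspm (3.13). Of 14 interferon response genes 5 were lower (camera adjusted p = 2.4e-08; adjusted p = 0.33 with an estimated correlation), with Ifi207 (−2.74) and Ifit1 (−2.04). Of 10 complement genes 2 were lower (camera adjusted p = 2.3e-06; adjusted p = 0.22 with an estimated correlation), C7 (−3.38) and C3 (−1.05). Cell cycle genes led 1 activated sub-cluster of 137 nuclei and interferon response genes 1 other sub-cluster of 108 nuclei. Without them, an alternative chosen after seeing the data, the cell cycle list no longer passed (camera adjusted p = 0.81), while interferon response did (0.0029), as did matrix proteins (6.1e-08) and complement (2.7e-04). Without doublet removal Bub1 (−1.98) and Aspm (−1.97) turned round. The cell cycle list then passed camera downward (adjusted p = 7.1e-13), as it did under the unrevised rules (1.8e-33), interferon response did not pass with list genes kept for clustering (0.87), and complement did not with the stricter filter (0.10), in settings added for the lists after seeing the data.

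Gpr39 was higher in activated fibroblasts by 1.78 (SE 0.183, edgeR adjusted p = 1.5e-05), at 338 ± 75.2 against 111 ± 83.5 CPM (SD, n = 4), in 4 of 4 libraries. This difference was 0.09 with neighbours from all nuclei and the unrevised naming rules. Among the growth factors, 6 of 19 were higher, with neuregulin, Nrg1 (2.14), and Pdgfc (1.95), and placental growth factor, Pgf, was lower (−2.73). In the TGF-beta pathway 4 of 16 were higher, with thrombospondin, Thbs1 (2.73), and Tgfb3 (1.25), and Tgfbr3 (−1.90) and Ltbp1 (−1.85) were lower. The collagen-modifying enzymes P4ha3 (2.93) and Loxl3 (2.33) were among 3 of 20 crosslinking and turnover genes that were higher, and the aggrecanase Adamts5 was lower (−1.25). The ligand Gas6 (1.84) was higher and its receptor Axl (−1.09) lower. Il6 (1.77) and Pfkl (1.03) were higher, and Cxcl14 (−2.60) was lower. Outside the lists, Ccn4 (3.86), Col8a2 (2.69), Fgd6 (2.48) and Rflnb (2.44) had the largest rises. Icosl (−2.70), Clec3b (−2.43), Ms4a4d (−2.31) and Kcnip3 (−2.30) had the largest falls.

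The other 12 lists in fibroblasts had camera adjusted p between 0.11 (matrix crosslinking) and 0.85 (lysosome). In all, 303 genes were called higher and 208 lower in activated fibroblasts among 9565 counted. The counts were 31 higher and 64 lower under the unrevised rules, 88 lower with the stricter filter and 461 higher with no filter on low counts. Of the 511 calls, the unrevised rules kept 45, called 15 in the other direction and left 199 untested. Without library 2 the crosslinking list also passed (camera adjusted p = 0.0011 with the preset correlation). With all libraries and an estimated correlation that list stood at camera adjusted p = 0.90. Single libraries decided the calls of Il6 (edgeR adjusted p = 0.13, 0.16 and 0.055 without libraries 1, 3 and 4), Pfkl (0.91 and 0.93 on the log2 scale without libraries 1 and 3) and C3 (−0.81 without library 4). The stricter filter ended the calls of C3 (−0.00), Thbs1 (0.27), Nrg1 (0.45), Adamts5 (−0.49), Tgfb3 (0.52), Axl (−0.89), Pfkl (0.69), Rflnb (0.99), Il6 (1.54), Cxcl14 (−1.25) and Ifit1 (−1.70), and Ifit1 was higher (1.07) with list genes kept for clustering. The unrevised rules ended those of Fn1 (0.95), P4ha3 (0.88), Loxl3 (0.72), Tgfbr3 (−0.45), Col8a2 (0.33) and Fgd6 (0.34), and reversed Gas6 (−0.36) and Ltbp1 (0.24).

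Atp6v0d2 and Plin2 were higher and C4b lower in macrophages with Trem2 and Spp1 than in resident macrophages. Of 22 lysosome genes 4 were higher (camera adjusted p = 4.5e-05; adjusted p = 0.15 with an estimated correlation), with Atp6v0d2 at 4.94 (SE 0.391; 119 ± 74.4 against 3.50 ± 3.11 CPM, SD, n = 4) and Ctss at 1.32 (SE 0.132). Of 11 lipid handling genes 3 were higher (camera adjusted p = 0.0025; adjusted p = 0.15 with an estimated correlation), with the lipid droplet protein Plin2 (1.61) and the nuclear receptor Pparg (1.40). Of 5 complement genes measured among 15 listed, 2 were lower (camera adjusted p = 7.1e-06), with C4b at −2.73. Of 8 interferon response genes measured among 20 listed, 1 was lower (camera adjusted p = 0.0019), Oasl2 (−1.26). Both lists stood at camera adjusted p = 0.15 with an estimated correlation. In the TGF-beta pathway 2 of 13 were higher (camera adjusted p = 0.0096; adjusted p = 0.21 with an estimated correlation), Tgfbr1 (1.53) and Ltbp3 (1.35). Matrix proteins passed camera upward (adjusted p = 0.011; adjusted p = 0.44 with an estimated correlation) with no member called. Without a sub-cluster of 110 nuclei, set aside after seeing the data, that was also led by genes such as Reln and Tek, camera adjusted p was 0.082 for the TGF-beta pathway and 0.997 for matrix proteins, and it was 0.14 for matrix proteins without library 4. Neither list passed under any of 6 other filters on nuclei or clusterings, added for the lists after seeing the data (camera adjusted p between 0.086 and 0.29 for the TGF-beta pathway and between 0.087 and 0.995 for matrix proteins).

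Gpr39 stood at 34.5 ± 12.3 CPM in Trem2 and Spp1 macrophages and at 28.0 ± 12.0 CPM in resident ones (SD, n = 4; log2 fold change 0.04, edgeR adjusted p = 0.97). Its sign hung on single libraries, with −0.15, 0.81, −0.28 and −0.10 without library 1, 2, 3 and 4, and it was −0.92 at a resolution of 2. The phagocytic receptor Cd300lf (2.77) was higher, and the bridging ligands Gas6 (−1.15) and Pros1 (−1.06) were lower. The membrane protease Mmp14 (2.32) and Adamts2 (1.14) were higher, as were the chemokine Cxcl16 (1.05), the transcription factor Junb (1.08) and the growth factor Hgf (1.09). The chemokines Ccl6 (−1.76) and Ccl9 (−1.65) were lower. The other 10 lists had camera adjusted p between 0.14 and 0.78, with matrix crosslinking at 0.035 without library 4. Outside the lists, Anpep (2.98), Fam20c (2.95), Slc6a8 (2.85) and Ahnak2 (2.58) had the largest rises, and Hif3a (−2.17), Gpt2 (−1.92), Fam118a (−1.90) and Kifc3 (−1.79) the largest falls. In all, 78 genes were called higher and 54 lower among 4816 counted, and up to 162 higher and 122 lower with list genes kept for clustering. Without library 1, Pros1 (−0.93) and Cxcl16 (0.89) fell under the fold limit, as did Cxcl16 (0.90) and Adamts2 (0.89) without library 3 and Adamts2 (0.97) without library 4. Junb lost its call without library 1, 2 or 4 (edgeR adjusted p = 0.077, 0.058 and 0.092), and Hgf without library 2 (0.17) and by the DESeq2 Wald test (0.20). Ltbp3 and Adamts2 were not called with the stricter filter (0.76 and 0.18), at a resolution of 2 (0.69 and −0.17) or with list genes kept for clustering (0.30 and −0.28). Gas6 (−0.999) and Pros1 (−0.88) fell under the fold limit at a resolution of 2.

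Eci1 and Acaa2 were lower and Inhba and Egr1 higher in stressed than in the other cardiomyocytes. Of 18 fatty acid oxidation genes 3 were lower by call (camera adjusted p = 1.2e-18; adjusted p = 0.035 with an estimated correlation, but 0.17, 0.21, 0.17 and 0.20 without library 1, 2, 3 and 4), with Eci1 at −1.34 (SE 0.103; 30.1 ± 7.93 against 75.0 ± 16.2 CPM, SD, n = 4) and Acaa2 at −1.25 (SE 0.109), and the median of the list was −0.70. Fits without a library rest on fewer sums, so that loss does not show that 1 library carried the result. With the preset correlation the 7 lists that passed in stressed cardiomyocytes passed again without each library. Of 17 TGF-beta pathway genes 4 were higher (camera adjusted p = 1.3e-05; adjusted p = 0.11 with an estimated correlation), with the activin subunit Inhba at 2.93. Of 15 immediate early and heat shock genes 5 were higher, or 6 adjusted over the list alone (camera adjusted p = 1.9e-05; adjusted p = 0.11 with an estimated correlation), with Egr1 (2.40) and the small heat shock protein Hspb1 (1.74). Among 18 calcium handling and channel genes 4 were lower (camera adjusted p = 6.4e-04; adjusted p = 0.13 with an estimated correlation), with the potassium channels Kcnj2 (−1.50) and Kcnj3 (−1.28). In the glycolysis and hypoxia list 2 of 17 were higher, Pfkp (1.56) and the glucose transporter Slc2a1 (1.03), and in the crosslinking list 2 of 17, Adamts2 (1.20) and P4ha2 (1.02). These lists passed camera (adjusted p = 0.0031 and 0.0075; adjusted p = 0.13 and 0.26 with an estimated correlation). Oxidative phosphorylation passed camera downward (adjusted p = 6.7e-05; adjusted p = 0.26 with an estimated correlation) with none of 21 members called and a median of −0.33. At a resolution of 2 oxidative phosphorylation did not pass camera (adjusted p = 0.25), and under the unrevised rules neither it (0.78) nor crosslinking (0.058) did; with neighbours from all nuclei crosslinking did not (0.097).

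The largest rise among growth factors in stressed cardiomyocytes was that of Gdf15 (4.23; 11.4 ± 7.74 against 0.578 ± 0.202 CPM, SD, n = 4), a secreted stress-response factor, with Hbegf (2.04) also among 4 higher members of 17. Nrg1 (−1.16) and Pdgfd (−1.01) were lower. The collagens Col4a1 (1.84) and Col4a2 (1.38), the chemokine Cxcl12 (1.95) and the interferon response genes Ifit2 (1.32) and Xaf1 (1.25) were higher, and lipoprotein lipase, Lpl, was lower (−1.03). Gpr39 stood at 2.30 ± 1.51 against 3.37 ± 1.29 CPM (log2 fold change −0.62, edgeR adjusted p = 0.27). The other 9 lists had camera adjusted p between 0.066 and 0.83. Outside the lists, Efhd2 (2.97), Fhad1 (2.51), Cttnbp2nl (2.45) and Pdlim7 (2.03) had the largest rises, and Ctla4 (−2.02), Abhd18 (−1.84), Ehhadh (−1.69) and Hs3st5 (−1.67) the largest falls. In all, 321 genes were called higher and 245 lower among 10719 counted. At a resolution of 2 the counts were 147 and 121, and Eci1 (−0.65), Acaa2 (−0.72), Kcnj2 (−0.88), Slc2a1 (0.36), Adamts2 (0.84), P4ha2 (0.75), Xaf1 (0.50), Lpl (−0.52), Nrg1 (−0.13), Pdgfd (−0.81) and Hs3st5 (−0.87) were not called. The other cardiomyocytes included 1535 nuclei with a median of 2839 UMIs. Relative to the median cardiomyocyte sub-cluster, these were led by genes such as Gpc6, Ebf1 and the fibroblast marker Abca8a. The stressed state included a sub-cluster of 73 nuclei led by genes such as Fgf12 and Cntn2. Without it and the sub-cluster of 1535 nuclei, both set aside after seeing the data, 326 genes were higher and 270 lower. Cytokines, with 2 of 22 listed genes measured in the fit of all libraries, passed camera without library 2 (adjusted p = 0.048). Leaving out library 1 ended the calls of Lpl (−0.99), Slc2a1 (0.85), Pdgfd (−0.95), Xaf1 (edgeR adjusted p = 0.055) and Nrg1 (0.065). Leaving out library 3 ended those of Xaf1 (0.12) and P4ha2 (0.999 on the log2 scale), and library 4 those of P4ha2 (0.95) and Pdgfd (−0.97).

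**Figure D3:**
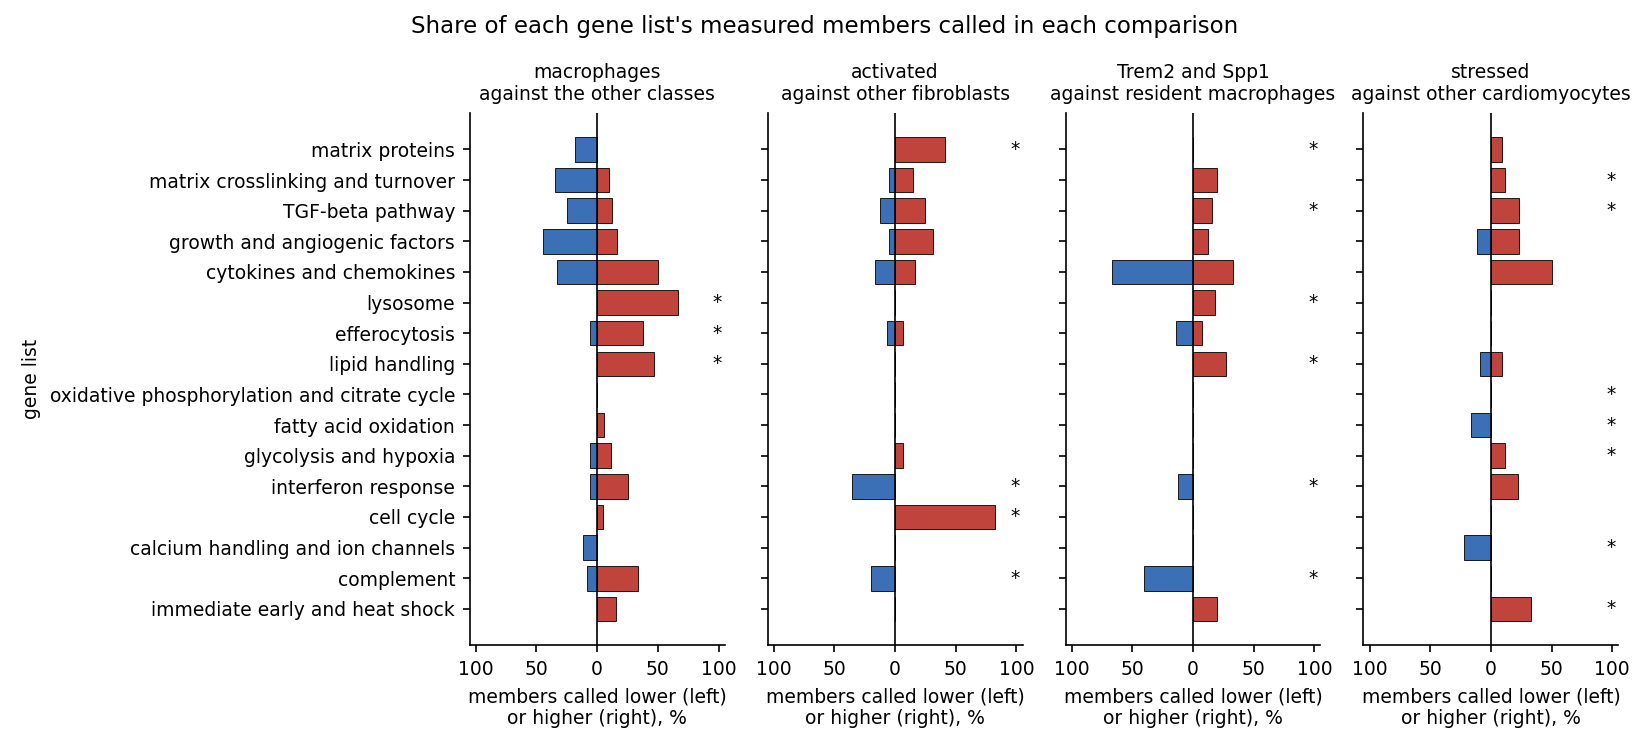
Share of each fixed list's measured members called lower (left, blue) or higher (right, red) in 4 comparisons (%, horizontal axes); an asterisk marks lists with a camera adjusted p under 0.05. Of the cell cycle list 19 of 23 members were higher in activated fibroblasts, and of the lysosome list 16 of 24 were higher in macrophages. In activated fibroblasts the cell cycle list did not pass with an estimated correlation (camera adjusted p = 0.33) or without a sub-cluster of 137 nuclei. Without doublet removal it passed downward.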

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

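The subtraction tests that give more weight to shallow nuclei, the ratios over all nuclei kept and those under the unrevised naming rules were chosen only after the result was seen. Of 31 quantities with 1 value per library, 5 had a library set apart from the others by Dixon's test at the 5% level, and chance alone sets apart about 1 in 20 such sets. Library 2 had 1.98% smooth muscle nuclei, against 1.02% to 1.17% in the others. Its Gpr39 level was 399 CPM in fibroblasts against 150 to 187 CPM, 25.7 CPM in endothelial cells against 15.6 to 16.2 CPM, and 37.2 CPM in pericytes against 18.8 to 19.7 CPM. Library 4 had 538 CPM of Y-linked transcripts against 0.224 to 0.681 CPM, and 0.424 CPM of Xist against 1025 to 1243 CPM; 18, 9, 6 and 12 nuclei of libraries 1 to 4 had UMIs of both, and the labels give no sex.

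Library 2 also held the highest shares of activated fibroblasts (78.2%) and of Trem2 and Spp1 macrophages (41.0%). Over all fibroblast nuclei, without clusters, its log2 ratio of activated to resting marker UMIs exceeded that of the next library by 1.31 (range of the other 3 libraries 0.73), by 1.44 after thinning each nucleus to 1000 UMIs (0.84), and by 1.32 and 1.34 after the cardiomyocyte level was subtracted as a stand-in for free RNA, unweighted and weighted by depth (0.73 and 0.75). The matching gaps for Trem2 and Spp1 against resident markers in macrophages were 1.25 (0.53), 1.06 (0.88), 1.23 (0.55) and 1.06 (0.60). Under the unrevised rules, with neighbours from all nuclei, library 2 had the lowest activated share (30.1% against 34.8% to 41.3%), and its ratio in the fibroblasts so named was 0.19 below the highest. The Trem2 and Spp1 share there was again highest in library 2 (72.9% against 10.7% to 21.0%). Over all nuclei kept, whatever their class, the gaps were 1.23 (0.47) for the fibroblast markers and 0.77 (0.56) for the macrophage markers. The activated share thus hung on the neighbour and naming rules, which the unrevised run changed together. For fibroblasts, the marker ratios over all nuclei argue against clusters that follow the library as the whole cause. For macrophages, the ratio ran from 0.20 to 1.54 over all nuclei and from −1.53 to 0.24 in the class. Other classes thus added to these UMIs, and the gap over all nuclei does not decide there. Within the class the gap of 1.25, which used no states, argues only against states that follow the library. The subtracted values argue against free RNA as the whole cause of the gaps in these ratios. Thinning gave each nucleus the same weight in the ratio, but classes and states were not named again at equal depth. It therefore does not decide whether depth shifted the shares. No biological explanation was tested, since all libraries belong to 1 group; a difference between the hearts, the infarcts or the tissue sampled stays open.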

How the results depend on the processing

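Drawing neighbours from all nuclei, the unrevised naming rules, setting sub-clusters aside, and tests of the lists under other filters, scaling or clusterings were chosen only after the result was seen; the other alternatives were set before the data were examined. Of 390 recomputed values that answer a comparison, 329 kept their direction and their side of the threshold or stayed within the spread, 55 moved, 3 lost a call, 2 gained one and 1 reversed. Of 2983 others, on single genes, single lists and levels, 2711 were kept, 182 lost a call, 54 gained one, 24 reversed and 12 moved. The mean of a share or of a Gpr39 level without 1 library can never leave the SD over 4 libraries. Those values, part of both tallies, were thus kept by construction and say nothing on stability. Gpr39 stayed called higher in fibroblasts (2.43 to 3.35) and lower in cardiomyocytes (−3.67 to −2.74) in all 16 fits. The cause was not tested for the changes below unless the setting itself shows it.

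With the stricter filter the fibroblast share was 19.3%, the unnamed share 14.8% and the activated share 17.6%, and 88 genes were lower in activated fibroblasts. Without doublet removal the endothelial share was 18.9%, the unnamed share 17.8% and the activated share 27.3%, and in activated fibroblasts Aspm (−1.97) and Bub1 (−1.98) reversed; 51 of the 511 calls there changed direction. At a resolution of 2 the stressed share was 49.9%, and Gpr39 was at 0.90 in smooth muscle and −0.28 in lymphatic cells. That setting gave 585 genes lower in macrophages, 119 higher and 86 lower in Trem2 and Spp1 macrophages, and 147 higher and 121 lower in stressed cardiomyocytes; Adamts2 (−0.17) and Gpr39 (−0.92) reversed between the macrophage states.

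With list genes kept for clustering the shares were 17.1% for cardiomyocytes, 19.3% for endothelial cells, 2.97% for lymphatic cells and 21.5% for unnamed nuclei, and 7.50% of macrophages had Trem2 and Spp1 and 48.8% were resident. Gpr39 was at −1.28 in macrophages, 0.72 in smooth muscle and −0.82 in lymphatic cells. Between the macrophage states 162 genes were higher and 122 lower, and Adamts2 was at −0.28; Ifit1 was at 1.07 in activated fibroblasts. With no filter on low counts, which tests more genes, 1526 were higher in macrophages, 461 in activated fibroblasts, and 129 higher and 108 lower in Trem2 and Spp1 macrophages.

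With neighbours from all nuclei the unnamed share was 10.7%, the activated share 26.8% and the Trem2 and Spp1 share 7.20%; Gpr39 was at −0.71 in lymphatic cells, 145 genes were higher and 117 lower between the macrophage states, and 128 were lower in stressed cardiomyocytes. With the unrevised rules as well, the shares were 14.6% endothelial, 10.6% fibroblast and 28.1% unnamed, and 24.5% of cardiomyocytes were stressed. Gpr39 was at −1.03 in macrophages, 0.61 in smooth muscle and −0.68 in lymphatic cells. Activated fibroblasts had 31 genes higher and 64 lower, with Gas6 (−0.36) and Ltbp1 (0.24) reversed, and stressed cardiomyocytes 190 higher and 126 lower.

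With sub-clusters set aside the cardiomyocyte share was 16.9% and the unnamed share 19.1%. Against 3 lists that passed camera in macrophages, 5 did with the stricter filter, at a resolution of 2, with neighbours from all nuclei and under the unrevised rules, 6 without doublet removal, with sub-clusters set aside and with no filter on low counts, and 8 with list genes kept. In activated fibroblasts 7 passed with neighbours from all nuclei. The cell cycle list reversed in activated fibroblasts without doublet removal (camera adjusted p = 7.1e-13) and under the unrevised rules (1.8e-33). In macrophages, where it had not passed (camera adjusted p = 0.98), it passed with the other sign without doublet removal (0.041) and with list genes kept (0.048). Between the macrophage states, where 5 of its 27 genes were measured, it had not passed either (camera adjusted p = 0.55). There it passed with the other sign at a resolution of 2 (camera adjusted p = 0.0080). Matrix proteins reversed between the macrophage states with the stricter filter (0.64), at a resolution of 2 (0.58), with list genes kept (0.20) and with neighbours from all nuclei (0.995).

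With an estimated correlation 0 lists passed in activated fibroblasts and 0 between the macrophage states, against 4 and 6 by camera with its preset correlation, and 1 against 7 in stressed cardiomyocytes. The estimate was above the preset 0.01 for lists such as matrix proteins in activated fibroblasts (0.69). For complement it was −0.092 in activated fibroblasts and −0.17 between the macrophage states, and for the TGF-beta pathway −0.033 in stressed cardiomyocytes. A higher correlation of the members therefore does not account for the loss of these lists. Fatty acid oxidation in stressed cardiomyocytes had an estimate of −0.019, yet its unadjusted camera p went from 7.6e-20 to 0.0022. With an estimated correlation, camera rests on the few residual degrees of freedom of 8 sums. The p-value can thus rise without correlated members. Leaving out 1 library at a time gave 3 to 6 passing lists in macrophages, a Gpr39 log2 fold change of −0.46 to 0.0082 in macrophages, and −0.28 to 0.81 between the macrophage states. The fit without a library term moved no count of calls or of passing lists by over 1.5 times. Of 35 splits of the 8 sums of a state comparison without a library term, only the real one gave 467 genes in fibroblasts (highest other 1), 122 in macrophages (0) and 433 in cardiomyocytes (0); of 40 drawn splits of the class sums, with the other classes taken as 1 group, only the real one, 1 split, gave 1073 (0), against 1597 genes where each class kept its own mean. With the library term, the 8 splits that part every library are too few for a share under 0.05 (real values 511, 132 and 566, highest other 0 each). Since the sums come from clusters of the same nuclei, the real split calls the most genes whatever the cause of the clusters, and no claim on chance rests on these splits. Fewer genes were tested between the macrophage states (6126) than in cardiomyocytes (12797).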

Other observations

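The test on Lypd1 and 2 of the alternatives used for mesothelial nuclei were chosen only after the result was seen, and the free RNA tests on Gpr39 in cardiomyocytes and macrophages were set beforehand. Mesothelial-type nuclei, which line the heart's surface, stayed unnamed because other classes' markers were present with Msln, Wt1 and Upk1b. The 4 clusters of this type, with 135, 92, 88 and 40 nuclei, had 540, 1120, 1080 and 379 CPM of Gpr39. Nuclei were named mesothelial in 6 alternatives, and in the 4 with enough of them for a test, 2 of these added after seeing the data, Gpr39 was higher in mesothelial nuclei than in the mean of the other classes by 4.46 to 5.12 on the log2 scale. Small clusters also held Schwann-type nuclei (56, with Sox10) and T or NK-type nuclei (67 in the largest, with Skap1 and Themis), both unnamed for the same reason. Another cluster of 15 nuclei was led by the skeletal muscle genes Myh3, Myh8 and Neb. Among the macrophages, 152 nuclei were led by Ciita and Ccr2 and 20 by Clec9a, genes of antigen-presenting cells, and these nuclei were counted as macrophages against the other classes. A dendritic class was named with the stricter filter (0.684% of nuclei) and at a resolution of 2 (0.646%). Among the fibroblasts, 52 nuclei were led by genes including Wif1 and Rspo3, which encode modulators of Wnt signalling.

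Growth factor genes of the macrophage class went both ways. Of 18 measured, 3 were higher by call, Pdgfc (3.21), Hgf (2.40) and Igf1 (2.17), and 8 were lower, with Pdgfd (−1.84), Pgf (−1.80) and Vegfc (−1.68) the lowest (camera adjusted p = 0.71). Among 12 complement genes, the receptors C3ar1 (5.13) and C5ar1 (4.78) were the highest of 4 higher members (camera adjusted p = 0.26). These genes were chosen after their values were seen.

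Gpr39 UMIs also appeared in cardiomyocyte and macrophage nuclei, and free RNA from fibroblasts is a candidate source. If so, Gpr39 would carry over from fibroblasts no more than the fibroblast markers do. Its ratio to the fibroblast level was 0.605 of the median ratio of those markers in cardiomyocytes and 0.722 in macrophages (medians over 4 libraries), so these UMIs may be background. In macrophages of library 4, Gpr39 stood at 19.0% of the fibroblast level, above the markers' 11.3%. In smooth muscle cells it stood at 31.7% against 29.7%, above the markers' median in 3 of 4 libraries, and the single markers there ran from 16.9% to 116%, so their median does not show what fibroblast RNA alone would give. The lowest marker stood at 1.29% in cardiomyocytes and 8.88% in macrophages, below Gpr39 (1.47% and 13.8%). Expression in any of these cells stays open.

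The higher Gpr39 level in fibroblasts could have come from reads of Lypd1, which lies on the opposite strand and overlaps its end. Lypd1 had 0.0101 UMIs per Gpr39 UMI in fibroblasts, but reads of Lypd1 counted as Gpr39 would also leave few Lypd1 UMIs, so the value does not decide and this explanation stays open.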
